A study of Homo sapiens with 8 samples.

How the data were processed

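Chromatin of T47D A1-2 and T47D MTVL WT cells was precipitated with a mix of 2 antibodies against GR (A1-2 only) or with an antibody against PR (both lines), after growth in hormone-stripped serum and serum starvation, per the labels' protocols. The libraries were sequenced on an Illumina Genome Analyzer, per the labels. The submitters' processing notes name Bowtie 1.1.1, MACS 1.4.2, bedtools and the hg19 build. How these were set, the control library used to call peaks, the read depth and any filter on reads are not given in the sources used here.

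Each of the 8 deposited files is a list of peaks called in 1 library, with chromosome, start, end and a score, and libraries were not pooled in them. The deposited score is the peak's own value, taken here as MACS's -10 times the log10 of the peak's p, since its lowest value over the lists is 100 and the deposited names give a threshold of 1e-10. It was used to describe, rank and filter peaks within a list and not to compare levels between libraries. In the strongest peaks the score reached a ceiling, with many peaks tied at or near 3100, so scores from 3100 up were not read as a ranking of sites. Positions are given counting from 1.

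Samples were grouped by their titles. Peaks outside chromosomes 1 to 22 and X were left out, and so were peaks that overlapped a peak of the A1-2 input list. Of 455 deposited GR peaks of untreated cells 394 were used, of 18538 GR peaks after Dex 18415, and of 1198 GR peaks after R5020 1185. Of the PR peaks of A1-2 cells 630 of 693 were used for untreated cells and 28262 of 28563 after R5020, and of those of MTVL cells 219 of 221 and 43070 of 43398. No input list of MTVL cells was used here. Peaks counted as shared when they overlapped by at least 1 bp. Shares have exact (Clopper-Pearson) 95% intervals. The overlap of unrelated lists was estimated by shifting the second list along each chromosome, with wrap-around, 100 times with a fixed seed, and by a shift of 5 kb for local density. Loss of MTVL PR sites in A1-2 cells was compared between sites at GR Dex peaks and elsewhere by the difference of shares and by a Mantel-Haenszel common odds ratio within deciles of the score. No p-value was computed, since peaks are not replicates. Runs of close peaks were peaks of an untreated A1-2 list, or of the GR R5020 list, in stretches of at least 5 with gaps of at most 20 kb, which made 33 regions, or 26 from the untreated lists taken without the GR R5020 list. Leaving out the 33 regions takes by construction a larger part of the lists that define them than of the others. That definition, and the separate count of chromosome 3 beyond 150 Mb, were chosen after seeing the data.

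The peaks named were fixed by rule as the 5 of highest deposited score in each class of a comparison, with ties in order of chromosome and position, of which the text gives the first ones. Runs of close peaks were named after their values were seen. Assigning peaks to genes was planned only for an annotation of the hg19 build. The gene table used here is of another build, so 0 genes were placed, peaks are named by position, and the planned distances to genes and counts near fixed gene lists were not run.

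Other settings chosen before the data were examined were a score of at least 200 (a p of 1e-20) in every list, input included, keeping peaks at input peaks, an overlap of at least 50% of the shorter peak, midpoints within 200 bp, lists of equal length, and leaving out peaks that overlap an untreated peak. Added after seeing the data were leaving out runs of close peaks, with or without chromosome 3 beyond 150 Mb, and strata of 50 classes of the score, of deciles within chromosomes and of quintiles within segments of 5 Mb, as well as no strata for the PR sites of A1-2 cells.

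The overlap and odds ratio steps were tested on simulated data. In simulated lists of 38542 peaks, 15440 shared peaks were made and 15440 were found, with 0 false overlaps, and bedtools 2.31.1 gave the same number. The simulated lists were thinned so that no peaks stood close together, and shared peaks were moved by less than the width of a peak. That setting made full recovery certain and left out peaks as close as those in runs. For the comparison of MTVL PR sites, an odds ratio of 5 built into 43398 simulated peaks was recovered as 4.96 (4.73 to 5.20). The simulated values depended on the score only through its deciles, with the same odds ratio in each. Recovery within those deciles was thus assured, and a ratio that differs between deciles was not simulated. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.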

Results

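The study mapped where the glucocorticoid receptor (GR) and the progesterone receptor (PR) bound the genome of T47D cells by ChIP-seq, in which DNA fragments held by a protein are recovered with an antibody and sequenced. T47D is an established human breast cancer line. A1-2 is the T47D derivative that the series describes as having both receptors, and MTVL WT is the T47D line that the labels name as the control. Cells were untreated or were exposed for 60 min to 10 nM dexamethasone (Dex), a synthetic glucocorticoid, or to 10 nM R5020, a synthetic progestin. GR was precipitated from A1-2 cells without hormone, after Dex and after R5020. PR was precipitated from A1-2 and from MTVL cells, each without hormone and after R5020. With input DNA of A1-2 cells, this made 8 libraries. Each condition had 1 library, so no difference between conditions has a replicate check and no p-value is given. Intervals are 95% intervals over peaks or regions and cover counting error only. The read depth of the libraries was unknown, and the number of peaks called in a library moves with its depth. Positions are in the hg19 build.

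Which receptor binding was present before hormone and after each ligand was read first from the number of called peaks. In A1-2 cells 394 GR peaks were called without hormone, 18415 after Dex and 1185 after R5020. The GR list after Dex was 46.7 times as long as the untreated list, and the GR list after R5020 was 3.01 times as long. At the same dose and time, Dex thus gave 15.5 times as many GR peaks as R5020, and with 1 library per ligand this ratio has no interval between libraries. PR peaks in A1-2 cells numbered 630 without hormone and 28262 after R5020. In MTVL cells they numbered 219 and 43070. The A1-2 input list held 1318 peaks. Peaks covered 13.5 Mb after Dex in the GR list and 1.69 Mb after R5020, against 20.4 Mb for PR in A1-2 cells and 32.1 Mb for PR in MTVL cells after R5020. High-scoring GR peaks after Dex, of 81 at 3100 or more, lay on chromosome 14 from 95737736 to 95739063 (score 3203) and on chromosome 1 from 215337891 to 215338548 (score 3187). With a score of at least 200 asked of every list, input included, the GR counts were 88, 8854 and 679 in the same order, and the Dex and R5020 lists were 100.6 and 7.72 times as long as the untreated list.

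**Figure D1:**
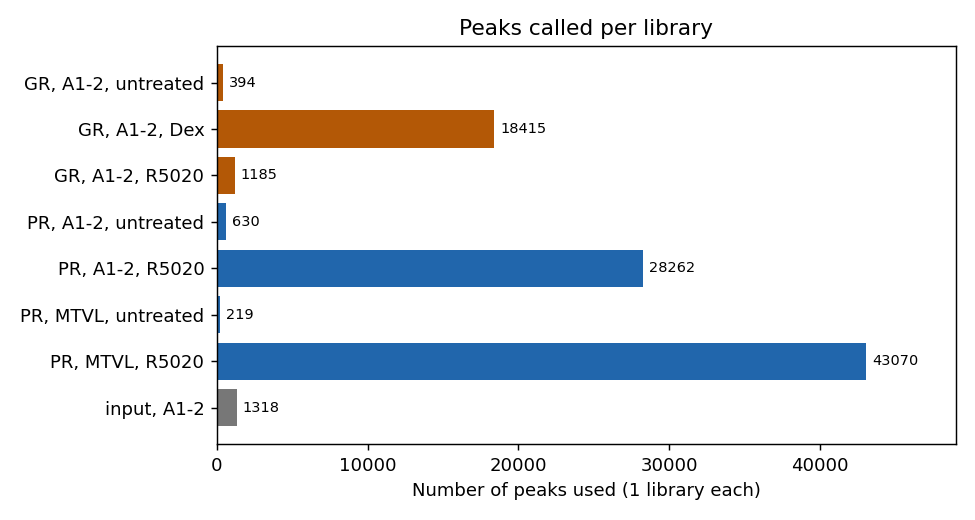
Number of peaks used per library (horizontal axis, 1 library per bar), with GR in orange, PR in blue and input in grey. Bars run from 219 peaks for PR in untreated MTVL cells to 43070 for PR in MTVL cells after R5020.

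Sites called without hormone were for the most part called again after Dex for GR and after R5020 for PR. Of the 394 GR peaks of untreated A1-2 cells, 71.6% (66.8 to 76.0) overlapped a GR peak after Dex, and 58.2% of 184 did outside 33 runs of close peaks, which are stretches of at least 5 peaks with gaps of at most 20 kb in an untreated A1-2 list or in the GR R5020 list. PR peaks after R5020 overlapped 74.4% of the 394 and 62.0% of the 184, so this overlap was not particular to GR. A shift of 5 kb left 29.4% and 6.52% at GR Dex peaks. Of the 630 untreated PR peaks of A1-2 cells, 76.5% (73.0 to 79.8) overlapped a PR peak after R5020, against 21.6% after a shift of 5 kb. Of the 219 untreated PR peaks of MTVL cells 218 overlapped a PR peak of MTVL cells after R5020. The untreated PR lists of the cell lines shared some sites. Of the untreated A1-2 PR peaks 61 (9.68%, 7.49 to 12.3) overlapped an untreated MTVL PR peak, and in the other direction 39 of 219 did (17.8%, 13.0 to 23.5, against 0.027% on average in shifted lists). Of the untreated A1-2 PR peaks 154 (24.4%, 21.1 to 28.0) overlapped an untreated GR peak of A1-2 cells. The strongest untreated PR peak of A1-2 cells, on chromosome 5 from 139930069 to 139930832 (score 2866), had a GR counterpart from 139930060 to 139930829 (score 2354). The strongest untreated PR peak of MTVL cells lay on chromosome 11 from 1817270 to 1818537 (score 511). Untreated peaks of A1-2 cells were narrow, with a median width of 226.5 bp for GR and 247.5 bp for PR, against 1242 bp for PR in untreated MTVL cells.

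Many of the untreated A1-2 peaks stood close together. The untreated A1-2 lists taken without the GR R5020 list gave 26 such runs, which held 48.2% of the GR peaks and 41.7% of the PR peaks. Of these runs, 8 lay on chromosome 16 between 34 and 36 Mb. That region held 116 GR peaks without hormone, 271 after Dex and 318 after R5020, and 123 PR peaks without hormone and 262 after R5020 in A1-2 cells. In MTVL cells it held 0 PR peaks without hormone and 3 after R5020, and the A1-2 input list held 0. The longest of the runs reached from 34590754 to 34833794, with 44 untreated GR peaks and 46 untreated PR peaks. Another run on chromosome 2, from 99524944 to 99555609, held 21 untreated GR peaks and 27 untreated PR peaks, 0 untreated MTVL peaks and 4 MTVL peaks after R5020.

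**Figure D2:**
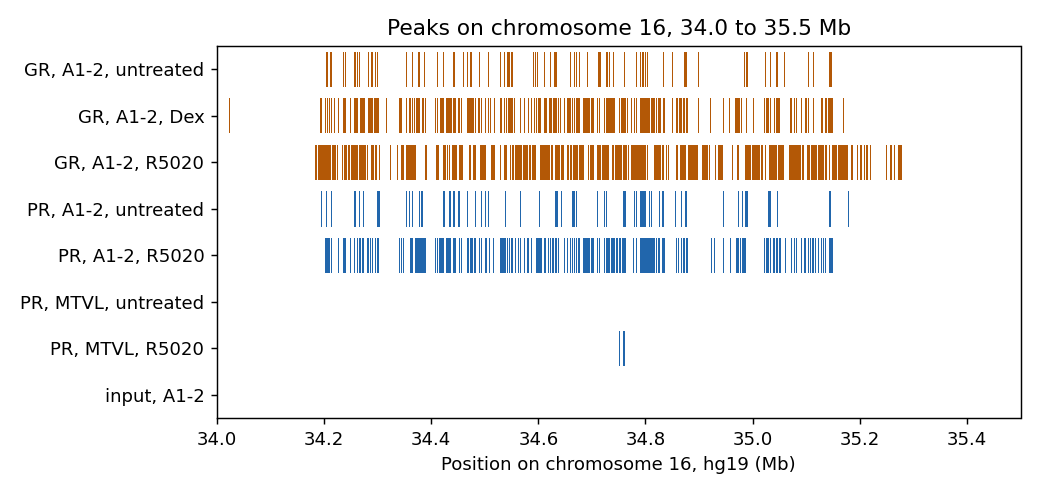
Peaks of each library (1 line per library) along chromosome 16, with position in Mb on the horizontal axis and GR in orange, PR in blue and input in grey; each bar is a peak, drawn at least 1.5 kb wide. The lists of A1-2 precipitates fill the region, whereas MTVL cells had 3 PR peaks after R5020 and the input list had 0.

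How far the receptors shared binding sites in A1-2 cells was compared at the PR peaks after R5020 and the GR peaks after Dex. Of the 28262 PR peaks, 13614 overlapped a GR Dex peak (48.2%, 47.6 to 48.8). Of the 18415 GR Dex peaks, 13590 overlapped a PR peak (73.8%, 73.2 to 74.4). Lists shifted along the chromosomes overlapped at 0.982% on average for PR peaks and at 1.496% for GR peaks, with 1.45% and 1.87% as the highest of 100 shifts. Overlapping peaks were nearly concentric, with a median distance of 40 bp between midpoints. Sharing went with strength. Among PR peaks, 20.5% of the lowest-scoring decile and 95.6% of the highest-scoring decile lay at a GR Dex peak. Among GR Dex peaks, 47.5% of the lowest decile and 98.6% of the highest lay at a PR peak.

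Of the A1-2 PR peaks 659 scored 3100 or more, a range in which the score no longer ranks sites. Among the shared sites in that range were those on chromosome 12 from 31973653 to 31974357, on chromosome 2 from 105097733 to 105098465 and on chromosome 11 from 85800630 to 85801310, with scores of 3226, 3216 and 3214. Sites of PR without a GR Dex peak numbered 14648 and had a median score of 172, against 452 for the shared PR peaks. The strongest of them lay on chromosome 20 from 3998643 to 3999765 (score 3100) and on chromosome 8 from 81665046 to 81666427 (score 3073). GR Dex peaks without a PR peak numbered 4825 and had a median score of 136, against 236 for the shared ones. The strongest lay on chromosome 6 from 167312015 to 167316199 (score 2637) and on chromosome 8 from 143884133 to 143886079 (score 2229). Because weak peaks fall on either side of a calling threshold, the number of sites held by 1 receptor depends on depth, which was unknown.

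**Figure D3:**
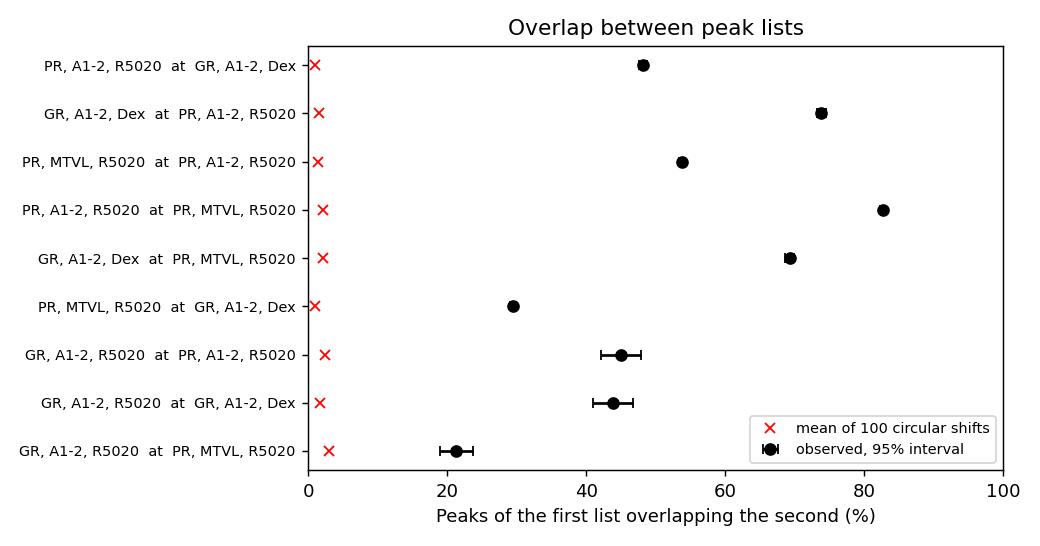
Share of the peaks of a first list that overlapped a second list by at least 1 bp, in percent (horizontal axis), for 9 pairs of lists. Black points are the observed shares with exact 95% binomial intervals, and red crosses are the means of 100 circular shifts, which lie between 0.932% and 2.95%.

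GR peaks after R5020 were compared with the PR peaks after R5020 and with the GR peaks after Dex, to see which sites the GR antibodies recovered under a progestin. Of the 1185 GR R5020 peaks, 455 (38.4%, 35.6 to 41.2) lay at sites of both, 78 at a PR site only, 65 at a GR Dex site only and 587 (49.5%, 46.7 to 52.4) at neither. In total 45.0% (42.1 to 47.9) lay at PR peaks and 43.9% (41.0 to 46.8) at GR Dex peaks. Circular shifts reached 14.4% and 8.61% at most, and a shift of 5 kb left 23.9% and 23.5%. Outside runs of close peaks the shares were 40.6% and 36.5%, against 9.19% and 7.27% after a shift of 5 kb. Conversely, 588 of the GR Dex peaks (3.19%, 2.94 to 3.46) lay at a GR R5020 peak, and outside runs of close peaks, which by definition hold many GR R5020 peaks, 303 of 18010 did (1.68%, 1.4996 to 1.88). In the highest-scoring decile of the GR Dex list the shares were 8.47% and 6.77%. The shares of GR R5020 peaks depended on the rule of overlap and on list length. These peaks were wide, with a median of 978 bp against 659 bp for GR Dex peaks. Where they overlapped, the median distance between midpoints was 367.5 bp to PR peaks and 350.5 bp to GR Dex peaks. An overlap of at least 50% of the shorter peak put 54.8% at neither, and midpoints within 200 bp put 73.7% there. Lists of equal length, taken by score, shortened the PR and GR Dex lists and put 85.0% at neither.

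The GR R5020 list was uneven along the genome. Chromosome 16 held 29.6% of its peaks and chromosome 3 held 12.5%, against 5.21% and 7.15% of the PR peaks of A1-2 cells and 4.70% and 12.1% of the input peaks. Chromosome 3 beyond 150 Mb held 7.28% of the input peaks, against 2.33% of the A1-2 PR peaks and 2.42% of the GR Dex peaks. The 33 runs of close peaks held 456 GR R5020 peaks, and 103 others lay on chromosome 3 beyond 150 Mb. Outside both, 626 GR R5020 peaks were left, of which 244 lay at PR and GR Dex sites, 44 at a PR site only, 15 at a GR Dex site only and 323 (51.6%, 47.6 to 55.6) at neither. The 244 peaks at shared sites fell on strong sites, since the PR peaks of A1-2 cells they overlapped had a median score of 2190 and the GR Dex peaks one of 562, against 244 and 193 for the whole lists. Over the whole list the median score was 258 (220 to 304) for the 587 peaks at neither and 211 (197 to 239) for the 455 at both. The 95 peaks at neither on chromosome 3 beyond 150 Mb had a median score of 127, and with these and the runs left out the medians were 374 for the 323 and 178 for the 244. Of the 323, 66 scored 1000 or more, compared with 18 of the 244. High-scoring peaks among the 323 lay on chromosome 1 from 27018357 to 27020151, from 27021512 to 27022650 and from 51984687 to 51985718, each with a score of 3100.

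**Figure D4:**
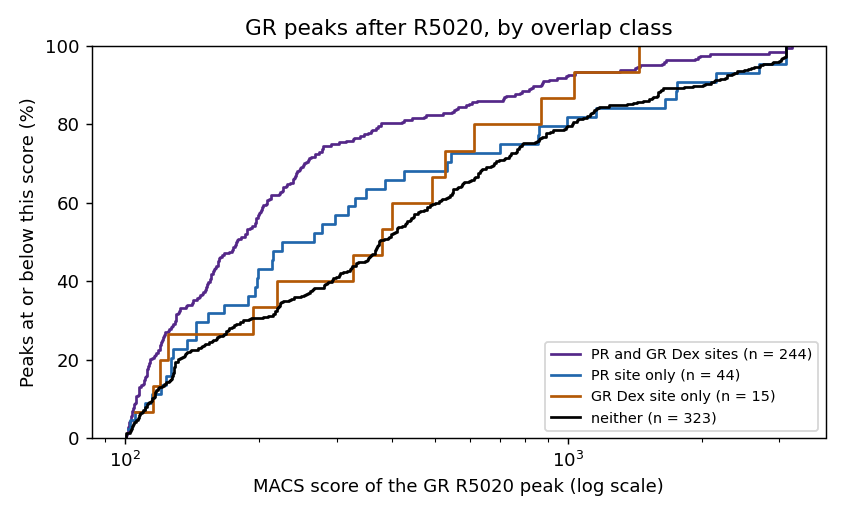
Cumulative share of GR R5020 peaks (vertical axis, percent) by the score of the peak (horizontal axis, log scale), for the 626 peaks outside runs of close peaks and outside chromosome 3 beyond 150 Mb. Lines are the 4 classes of overlap, and the line of the 323 peaks at neither PR nor GR Dex sites lies to the right of the line of the 244 peaks at both.

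The cell lines were compared by their PR peaks after R5020. Of the 28262 PR peaks of A1-2 cells, 82.7% (82.3 to 83.2) overlapped a PR peak of MTVL cells. Of the 43070 PR peaks of MTVL cells, 53.8% (53.3 to 54.3) overlapped a PR peak of A1-2 cells. Shifted lists gave 2.15% and 1.39%. The 19898 MTVL peaks without an A1-2 peak had a median score of 186, against 623 for the 23172 found in both lines, and the share found in A1-2 cells went from 18.9% in the lowest decile of the MTVL score to 97.6% in the highest. Strong exceptions existed on both sides. High-scoring MTVL peaks without an A1-2 peak lay on chromosome 13 from 109507154 to 109508627 (score 3228) and on chromosome 9 from 13063783 to 13065285 (score 3192). High-scoring A1-2 peaks without an MTVL peak lay on chromosome 1 from 177558232 to 177559369 and on chromosome 11 from 70823423 to 70824709, both with a score of 3100.

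Whether PR binding in A1-2 cells differed from that in MTVL cells at sites of GR is the question that the title of the series raises. PR sites of MTVL cells that lay at an A1-2 GR Dex peak were more often found in A1-2 cells than the others. Of 12708 such sites 11606 were found (91.3%, 90.8 to 91.8), and of 30362 other sites 11566 were found (38.1%, 37.5 to 38.6), a difference of 53.2 percentage points (52.5 to 54.0). Sites at GR Dex peaks were also the stronger ones in MTVL cells, with a median score of 776 against 244. Within deciles of the MTVL score the common odds ratio was 12.1 (11.2 to 13.0), compared with 17.1 without deciles. A common odds ratio averages over the deciles, and whether the ratio was equal in each was not tested. In the lowest decile 63.6% of the sites at GR Dex peaks and 12.7% of the others were found in A1-2 cells, and in the highest decile 99.7% and 91.3%. At a score of at least 200 in every list the common odds ratio was 18.2. The GR sites were mapped after Dex, not R5020. They were called in A1-2 cells, as were the PR peaks by which a site counted as found. These ratios therefore cannot part GR sites from sites that A1-2 libraries call more easily. GR R5020 peaks outside runs, also from A1-2 cells, gave a common odds ratio of 3.47 (1.92 to 6.26) within deciles.

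**Figure D5:**
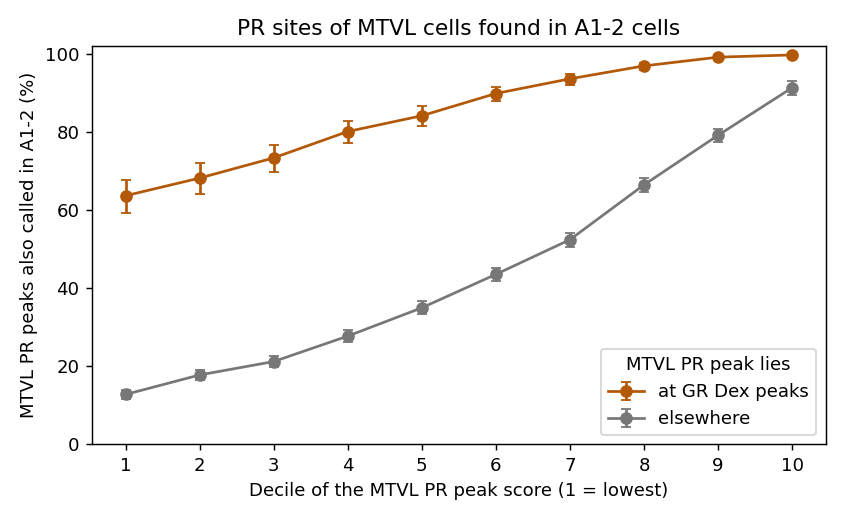
Share of MTVL PR peaks that were also called in A1-2 cells (vertical axis, percent), by decile of the MTVL peak score (horizontal axis, 1 the lowest), for peaks at GR Dex peaks (orange) and elsewhere (grey), with exact 95% binomial intervals. The peaks at GR Dex peaks lie above the others in each of the 10 deciles.

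The opposite view started from the PR peaks of A1-2 cells. Of those at GR Dex peaks, 85.6% (85.0 to 86.2) were also MTVL PR sites, compared with 80.0% (79.4 to 80.7) of the others, a crude odds ratio of 1.49. Within deciles of the A1-2 score the direction turned, with a common odds ratio of 0.501 (0.465 to 0.540), so that among A1-2 PR peaks of similar score those at GR Dex peaks were less often MTVL sites. Of the 4883 PR peaks that A1-2 cells had and MTVL cells did not, 1957 (40.1%, 38.7 to 41.5) lay at a GR Dex peak. Of the 23379 that MTVL cells also had, 49.9% (49.2 to 50.5) did. GR Dex peaks without an A1-2 PR peak were MTVL PR sites in 22.9% (21.7 to 24.1) of 4825 cases, compared with 85.8% (85.2 to 86.3) of the 13590 with one.

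Merged over the PR peaks of both lines after R5020 and the GR Dex peaks, the lists made 51444 regions. PR in MTVL cells alone accounted for 18796 of them (36.5%). Regions with PR in both lines and GR numbered 11528 (22.4%), and regions with PR in both lines but no GR Dex peak numbered 11505 (22.4%). GR Dex alone held 3719 regions, PR of A1-2 cells alone 2926, GR Dex with PR of A1-2 cells 1880, and GR Dex with PR of MTVL cells 1090.

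The chromosomes differed in how the lists were spread over them. The share of PR peaks on chromosome 16 was 1.79 times as high in A1-2 as in MTVL cells (1.67 to 1.93), and 1.49 times (1.38 to 1.61) without runs of close peaks. Chromosomes 20 (1.58, 1.45 to 1.72), 14 (1.42, 1.32 to 1.53), 19 (1.29, 1.17 to 1.43) and 11 (1.24, 1.17 to 1.32) also held larger shares of the A1-2 list. Chromosomes 21 (0.626, 0.540 to 0.727), 4 (0.779, 0.726 to 0.836) and 13 (0.801, 0.731 to 0.878) held the smallest relative shares. Chromosomes 17, 18, 6, 5, 2, 12, 7 and 1 also held smaller ones, with ratios from 0.832 to 0.929 and intervals below 1. Of the MTVL PR peaks on chromosome 20, 73.3% were found in A1-2 cells, compared with 37.4% on chromosome 21. Between receptors in A1-2 cells the spread was more even. The share of GR Dex peaks was 1.20 times that of PR peaks on chromosome 16 (1.11 to 1.29) and 1.14 times on chromosome 20 (1.04 to 1.25), and it was 0.809 times on chromosome 4 (0.734 to 0.891) and 0.815 times on chromosome 19 (0.718 to 0.925). These intervals were not adjusted for the 23 chromosomes compared, and copy number of the chromosomes was not analysed here.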

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

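The overlap of input peaks with receptor peaks was a test chosen after the data had been seen. The A1-2 input list held sites that the PR antibody recovered from the other cell line. Of its 1318 peaks, 318 (24.1%, 21.8 to 26.5) overlapped a PR peak of MTVL cells after R5020, against 4.17% on average and 5.39% at most in 100 shifts. The shares were 21.1% for PR peaks of A1-2 cells after R5020 and 8.12% for GR peaks after Dex, against 2.74% and 1.78% on average in shifts. The overlap was thus not particular to the other cell line or to PR. All peaks at input peaks were left out of the comparisons between lists, except where they were kept as an alternative.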

How the results depend on the processing

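The alternatives without runs of close peaks, the strata other than deciles, the ratios of peak numbers and the tests on the odds ratio of A1-2 PR sites were chosen only after the results were seen. Of 107 alternatives over 23 results, 52 stayed within the main value's 95% interval, or within 1.5 times for counts and their ratios, 54 moved further, and 1 reversed. The reversal was that of the A1-2 PR sites, whose odds ratio of being MTVL sites at GR Dex peaks was 0.501 within deciles of the score and 1.49 without strata. A1-2 PR peaks at GR Dex peaks scored higher than the others (median 452 against 172), and so did those at MTVL sites (292 against 138). The ratios of 0.501 and 1.49 came from the same 28262 peaks and differed only in the strata of the A1-2 score. The reversal therefore came from holding that score fixed. At a score of at least 200 in every list, input included, the counts were 88, 8854 and 679 for GR (untreated, Dex, R5020), 231 and 16594 for PR in A1-2 cells (untreated, R5020) and 58 for untreated MTVL cells, by construction lower, and Dex and R5020 gave 100.6 and 7.72 times the untreated number of GR peaks. That setting put 42.1% of A1-2 PR peaks at GR Dex peaks and 78.8% of GR Dex peaks at PR peaks, 31.1% of GR R5020 peaks at PR peaks, 30.2% at GR Dex peaks and 63.9% at neither, and 49.4% of MTVL PR peaks at A1-2 PR peaks and 86.2% in the other direction. It gave a common odds ratio of 18.2 for MTVL PR sites found in A1-2 cells, one of 0.358 for the A1-2 PR sites, a share ratio of 1.30 for GR Dex over PR on chromosome 16 and of 1.32 for A1-2 over MTVL PR on chromosome 14. In the same order of shares, midpoints within 200 bp gave 44.5%, 68.4%, 20.6%, 21.0%, 73.7%, 50.3% and 76.6%, with a common odds ratio of 10.4, and lists of equal length gave 60.9%, 61.2%, 12.5%, 11.6%, 85.0%, 68.5% and 69.4%. Leaving out untreated peaks gave 73.0% of GR Dex peaks at PR peaks, 34.2%, 35.4% and 57.2% for the GR R5020 peaks and 53.3% of MTVL PR peaks at A1-2 PR peaks. An overlap of 50% of the shorter peak gave 39.9%, 39.0% and 54.8% for the GR R5020 peaks. Without the 33 runs of close peaks 184 untreated GR, 342 untreated PR and 729 GR R5020 peaks were left in A1-2 cells, the GR R5020 shares were 40.6%, 36.5% and 57.3%, and 83.8% of A1-2 PR peaks were MTVL sites. Since runs were defined on the untreated and GR R5020 lists, it is by construction that Dex then gave 97.9 times the untreated number of GR peaks and 24.7 times that of R5020. The chromosome 16 ratio was 1.49 and the odds ratio of the A1-2 PR sites 0.569. Quintiles of the score within 5 Mb segments gave a common odds ratio of 10.6 for MTVL PR sites. Apart from shorter lists, the definition of runs and the strata behind the reversal, the cause was not tested. The planned results on distances to genes and on fixed gene lists, with their alternatives, were not run. Depth was unknown and limits each count of sites held by 1 list.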

Other observations

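The tests of lower PR at GR sites, of runs of close peaks, of weak calls, of another precipitate, of the PR antibody's target and of extra copies were chosen only after the results were seen.

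A few runs of close peaks set the PR antibody apart from the GR antibodies in the absence of hormone. On chromosome 5 from 180600614 to 180649639, the untreated PR lists held 9 peaks in A1-2 and 3 in MTVL cells, and the GR lists held 0 untreated, 0 after Dex and 0 after R5020. On chromosome 6 from 26521295 to 26572180 the PR lists held 7 and 3 untreated peaks, and the GR lists again 0, 0 and 0. Of the 26 runs of the untreated A1-2 lists, 5 held an untreated PR peak of MTVL cells, and none of those 5 held an untreated GR peak. One of the 5, on chromosome 6 from 26286625 to 26330744, held 2 GR peaks after Dex. What genes or repeats lie at these positions was not analysed here. Outside the 33 runs of the untreated and GR R5020 lists together, 342 untreated PR peaks of A1-2 cells were left, of which 46 (13.5%, 10.0 to 17.5) overlapped an untreated MTVL PR peak and 62 (18.1%, 14.2 to 22.6) an untreated GR peak.

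MTVL PR sites were found in A1-2 cells more often at GR Dex peaks than elsewhere. Strength of the peak in MTVL cells is argued against as the whole cause by a common odds ratio of 12.01 (11.2 to 12.9) within 50 classes of the MTVL score. Differences between 5 Mb segments are argued against likewise by one of 10.6 (9.82 to 11.5) within segments and quintiles of that score. Copy number itself was not measured, and changes shorter than 5 Mb were not held fixed. Strength in A1-2 cells was not held fixed either, so these ratios do not decide on it. It stays open that some sites are called more easily in any A1-2 library, since GR R5020 peaks outside runs marked the MTVL sites found in A1-2 cells too, with a common odds ratio of 3.47 (1.92 to 6.26) over 239 MTVL peaks. A candidate explanation, as a hypothesis, is that both receptors take the sites that A1-2 chromatin leaves open, but the GR R5020 list is itself a receptor list and 1 library per condition cannot part this from library quality. Whether PR is lower at GR sites in A1-2 cells stays open as well. The common odds ratio of 12.1 within deciles rests on GR Dex peaks that were themselves called in A1-2 cells, and a lower level that keeps its call would not change it. The common odds ratio of 0.501 (0.465 to 0.540) from the A1-2 PR peaks does not decide it either. It too rests on GR Dex peaks called in A1-2 cells, and it leaves out PR sites that A1-2 cells lack. Without strata, which leaves the A1-2 score free, it was 1.49.

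With midpoints within 200 bp, 73.7% of the GR R5020 peaks lay at neither PR nor GR Dex sites. By an overlap of at least 1 bp, which is used below, about as many lay at neither as at them. Runs of close peaks and chromosome 3 beyond 150 Mb are argued against as the whole cause, since 323 of the 587 such peaks lay outside both. Weak calls are argued against as the whole cause, since the median score of the 587 was 258 (220 to 304), not below the 211 (197 to 239) of the 455 peaks at PR and GR Dex sites. They remain a candidate explanation for the 95 such peaks on chromosome 3 beyond 150 Mb, whose median was 127 (120 to 139), in a stretch that also held 7.28% of the input peaks. Peaks of that stretch outside runs that lay at both PR and GR Dex sites scored 103, 108, 109, 115, 120, 133 and 292, and a peak at a PR site only scored 397. A low score there was therefore not particular to peaks at neither. Reads from another precipitate in this library stay open and cannot be told apart from GR binding under R5020, since no list of an unrelated antibody was used here and the 20 of the 323 at PR peaks of MTVL cells decide nothing in a class defined by lacking A1-2 PR peaks.

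Runs of close peaks filled part of chromosome 16 in each A1-2 receptor list and not in MTVL cells. Recovery by the PR antibody alone is argued against, since of 22 runs of the untreated A1-2 PR list without an untreated MTVL peak 21 held an untreated GR peak. Extra copies in A1-2 DNA stay open, although 0 of the 26 runs of the untreated lists held an input peak. Peaks at input peaks were left out before runs were defined, which by construction lowers that count. On chromosome 16 between 34 and 36 Mb the input list held 0 peaks, so no peak was left out there for that reason. The control used to call the input peaks is also not given in the sources used here. Extra copies and a property of A1-2 chromatin therefore cannot be told apart. Neither repeated sequence in these regions nor the difference between the cell lines that the labels name was tested as a cause. The deposited MTVL lists held 0 peaks outside chromosomes 1 to 22 and X, and the A1-2 lists held from 1 (GR R5020) to 20 (untreated GR and input). Whether the lists of both lines were processed alike is not given in the sources used here. That was not tested as a cause either.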
